A study of Rattus norvegicus with 9 samples.

How the data were processed

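RNA of rat heart tissue was sequenced in 9 libraries, 3 each of WKY, SHR and SHR given allisartan by gavage for 34 weeks. Per the labels' protocols, RNA was extracted with the mirVana kit (Ambion) and libraries were made with the TruSeq stranded mRNA kit (Illumina). The table deposited by the authors gives an FPKM value (fragments scaled by transcript length and by the library's mapped fragments) per gene and library, with no further normalization recorded. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq were used with build Rnor_6.0. The versions, the role of each tool and the gene models are not given in the sources used here. The unit was checked on the values, which are not whole and sum to 359207 to 388172 per library, so they are neither counts nor TPM. Read counts were not used here and the depth of each library is unknown, so no counting interval or detection limit is given. The 10 most abundant genes held 13.5% to 16.6% of a library's FPKM. Of 22601 genes in the table, 20633 (91.3%) were matched by gene identifier to a reference table on another build, which was used for names and genomic spans. Spans were found for 98.2% of tested genes. Symbols of 27 genes had been turned into dates in the table and were replaced by the reference's symbol through the identifier.

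Each library was divided by 1 median-of-ratios factor taken over the 9194 genes at 1 FPKM or more in all 9 libraries. The factors were 0.965 to 1.04. Genes at a rescaled FPKM of 0.5 or more in at least 3 libraries were kept, which left 11717. A pseudocount of 0.5 was added before taking log2. R 4.3.3 with limma 3.58.1 fitted 1 mean per group to all 9 libraries (6 residual degrees of freedom) with a variance trend, and gave 3 contrasts: SHR minus WKY, treated SHR minus SHR and treated SHR minus WKY. P-values were two-sided and adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Gene groups were tested with camera from limma, with a preset correlation between genes of 0.01 and again with an estimated one. Of 44 lists, the 33 with at least 5 tested members were tested, and adjusted together within a contrast. The counts adjusted over the list alone use the members of a list only. Pathways of 15 to 200 tested genes in the annotation deposited with the table were tested the same way, which was added after the data were seen. Gstm2 was also tested with an exact permutation test. Opposite movement of both SHR contrasts was compared with 100 simulations of groups without a difference. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

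The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per contrast, up to 10 genes with the largest rise and up to 10 with the largest fall among called genes with a mean of 1 FPKM or more in a group, no overlap between groups and an established symbol. It also named up to 4 called members of each list (the 2 with the smallest p where none was called) and a panel given in every contrast: Gstm2, Cd36, Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Tgfb1, Agtr1a, Ace, Agt, Nqo1 and Hmox1. Alternatives were no rescaling, quantile normalization, a pseudocount of 1 or 0.1, no filter on low values, robust moderation, array weights, only the 6 libraries of a contrast, a replicate block, leaving out each library, a minimum log2 change of 1 and the estimated correlation. Cyclic loess normalization and removal of the trend with genomic span were added after the data were seen. The list of long-transcript genes was also written then.

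The procedure was tested on simulated data with known changes in a set of genes. With log2 changes of 0.5, 1 and 2, it recovered 53.7%, 98.5% and 100.0% of changed genes for SHR minus WKY, 53.7%, 92.5% and 100.0% for treated SHR minus SHR, and 50.7%, 97.0% and 98.5% for treated SHR minus WKY. It called 0.0716%, 0.0358% and 0.0806% of unchanged genes. A shifted complement list was recovered in each contrast, and of the other lists 1 was called in SHR minus WKY and 0 in each other contrast. The complement list has 4 members that are also in another list, so not all other lists were wholly unshifted. The simulated genes were drawn independently, so these runs do not show how often lists of correlated genes are called falsely. Not tested, with under 5 tested members, were the lists of mitochondrially encoded genes (0 in the table), and of T cell (4 tested members), B cell (0), neutrophil (2), mast cell (3), platelet (4), adipocyte (4), mesothelial (1), chondrocyte-like (2), skeletal muscle (3) and thymus and lymph node (4) markers.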

Results

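Gene expression was measured by RNA sequencing in heart tissue of 48-week-old rats. There were 3 groups with 3 libraries each. Wistar Kyoto rats (WKY) are a strain with normal blood pressure, and spontaneously hypertensive rats (SHR) develop high blood pressure without treatment. The last group, called treated SHR here, were SHR given allisartan, a blocker of the angiotensin II type 1 receptor, by mouth for 34 weeks. Rats of the WKY and SHR groups received water alone by the same route. Gene values are the deposited FPKM after 1 rescaling factor per library, given as mean ± SD over the 3 libraries of a group (n = 3 throughout). Log2 changes are differences of group means of log2(rescaled FPKM + 0.5), a scale that understates the change of low genes. Sequencing depth is unknown. Between 14279 and 14948 genes were listed above 0 per library, with 14489 to 14677 in WKY, 14844 to 14948 in SHR and 14279 to 14538 in treated SHR. Across genes, correlations of the log2 values were 0.985 to 0.990 for the 9 pairs of libraries within a group and 0.961 to 0.975 for the 27 pairs between groups. The labels do not state that each library came from its own animal, so p-values measure the spread between these libraries, which may be in part technical. The first 2 principal components held 36.5% and 28.6% of the variance. On the first SHR lay at 23.3 to 32.9, WKY at -10.4 to -6.41 and treated SHR at -22.4 to -13.8. On the second WKY lay at 21.9 to 26.1, SHR at -6.25 to -4.72 and treated SHR at -19.3 to -18.3, farther from WKY than SHR.

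The comparison of SHR with WKY asks how the heart of the hypertensive strain differs from that of the normotensive strain. Strain and hypertension go together in this design, so they cannot be told apart in either comparison with WKY. No blood pressure of these animals was used here. Genes of the extracellular matrix were among the largest rises. Thbs4, which encodes the matrix glycoprotein thrombospondin 4, was at 1.11 ± 0.169 in WKY and 49.8 ± 7.18 in SHR (log2 change 4.96, SE 0.277). Ltbp2, a latent TGF-beta binding protein, rose from 0.520 ± 0.141 to 12.8 ± 2.85, and Postn, which encodes periostin, from 1.71 ± 0.242 to 18.7 ± 2.18. The fibrillar collagen genes Col1a1 and Col3a1 rose by 2.09 and 2.11 (log2, SE 0.170 and 0.182), Col3a1 from 40.6 ± 8.42 to 174 ± 8.99. In the list of extracellular matrix and fibrosis genes, 40 of 48 tested members rose and 1 fell (44 and 1 adjusted over the list alone). The mean log2 change was 1.29 ± 1.02 (SD over genes, camera adjusted p = 1.04e-24, adjusted p = 0.168 with an estimated correlation). Tgfb1, the gene of the cytokine TGF-beta 1, rose from 10.1 ± 0.494 to 15.6 ± 1.87 (adjusted p = 0.00239). Among fibroblast markers 10 of 13 rose and 0 fell, 11 and 0 adjusted over the list alone, with Mfap5 and Mgp higher by 1.55 and 1.85 (camera adjusted p = 2.04e-09, adjusted p = 0.166 with an estimated correlation).

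Genes of the fetal cardiac programme, which are re-expressed in the overloaded heart, also rose. Acta1, skeletal alpha-actin, went from 633 ± 86.8 in WKY to 2612 ± 407 in SHR (log2 change 2.04, adjusted p = 7.35e-05). Nppa, the atrial natriuretic peptide gene, rose from 1872 ± 245 to 4289 ± 1507 (log2 change 1.15, adjusted p = 0.0118). Xirp2 rose by 0.98 and Myl4, the atrial essential light chain, by 0.93. Nppa and Myl4 are also in the list of atrial cardiomyocyte markers, of which 2 of 6 rose and 2 fell. Of the list of fetal and hypertrophy-associated cardiac genes, 11 of 18 tested members rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 6.1e-05, adjusted p = 0.208 with an estimated correlation). Nppb, the brain natriuretic peptide gene, was at 475 ± 70.4 in WKY and 698 ± 76.6 in SHR, which missed the threshold (adjusted p = 0.0536). It passed in 9 alternatives, among them without treated SHR replicate 1 (0.0314) or replicate 2 (0.0109), with 0.0109 to 0.174 over the alternatives. The beta-myosin heavy chain gene Myh7 fell by 0.39 and Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum, fell by 0.33 (adjusted p = 0.00559 and 0.00635). Both calls ended with cyclic loess normalization, which gave smaller falls of 0.21 for Myh7 (adjusted p = 0.0860; 0.00353 to 0.0860 over the alternatives) and 0.16 for Atp2a2 (0.109; 0.00388 to 0.109). Myh6, the alpha-myosin heavy chain gene, was at 1219 ± 192 and 1144 ± 295 (adjusted p = 0.686).

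The macrophage, complement and inflammatory lists were called up in SHR. All 14 tested macrophage markers rose (also adjusted over the list alone), among them Lyz2, lysozyme, from 83.6 ± 6.64 to 263 ± 27.6. Their mean log2 change was 1.00 ± 0.283 (camera adjusted p = 1.88e-12, adjusted p = 0.166 with an estimated correlation). Complement genes rose in 16 of 20 cases and fell in 0 (17 and 2 adjusted over the list alone; camera adjusted p = 2.47e-10, adjusted p = 0.168 with an estimated correlation). Serping1, which encodes the C1 inhibitor, rose by 1.55 and C1qb by 1.23. In the list of inflammatory cytokines and adhesion genes, 14 of 29 tested members rose and 0 fell (19 and 1 adjusted over the list alone). This list was the 1 of 33 in this comparison that also passed with an estimated correlation (camera adjusted p = 4.22e-06, adjusted p = 0.0473 with an estimated correlation). The monocyte chemokine genes Ccl7 and Ccl2 rose by 2.24 and 1.69. Of the genes of NADPH oxidase and other oxidant sources 5 of 10 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0318, adjusted p = 0.208 with an estimated correlation). Cybb, the catalytic NADPH oxidase subunit, rose by 1.08 and Maoa, monoamine oxidase A, by 1.29. The list's call was lost without SHR replicate 1 (adjusted p = 0.0812; 0.01003 to 0.0812 over the alternatives).

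Called lists of fuel use were those of fatty acids and oxidative phosphorylation, both down. Of the list of fatty acid uptake and oxidation, 0 of 40 tested members rose and 24 fell (0 and 26 adjusted over the list alone; camera adjusted p = 4.9e-13, adjusted p = 0.208 with an estimated correlation). Pdk4, the kinase that limits glucose oxidation, fell from 690.0 ± 69.4 in WKY to 199.7 ± 52.5 in SHR, and Ucp3, a mitochondrial uncoupling protein, from 12.0 ± 2.45 to 3.82 ± 0.573. The fatty acid transporter gene Cd36 was at 117 ± 24.4 and 56.4 ± 0.876 (log2 change -1.03, adjusted p = 0.0167). Its call was lost without WKY replicate 1 (0.0655) or SHR replicate 3 (0.0515), with 0.000900 to 0.0655 over the alternatives. Nuclear-encoded oxidative phosphorylation genes fell in 20 of 63 cases and rose in 0 (26 and 2 adjusted over the list alone), camera adjusted p = 2.77e-07, adjusted p = 0.488 with an estimated correlation. Cycs, the gene of cytochrome c, was at a log2 change of -0.49. The mean change of that list was -0.19, against -0.10 with quantile and -0.08 with cyclic loess normalization. Glucose uptake and glycolysis genes went both ways (7 of 28 rose and 10 fell, 8 and 12 adjusted over the list alone, camera adjusted p = 0.259). The list's mean of 0.08 and median of -0.15 differed in sign, with the test on the side of the median. Eno1, the glycolytic enzyme alpha-enolase, was at 43.7 ± 1.79 in WKY and 356 ± 18.4 in SHR (log2 change 3.01, SE 0.0677), and near-identical copies make its level uncertain.

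Of the ventricular cardiomyocyte markers 0 of 10 rose and 5 fell, 0 and 6 adjusted over the list alone (camera adjusted p = 0.00182, adjusted p = 0.208 with an estimated correlation). Fabp3, the heart fatty acid binding protein, was at 3371 ± 135 in SHR against 5451 ± 378 in WKY. The list's mean was -0.27, against -0.17 with quantile and -0.13 with cyclic loess normalization, and its call ended with quantile normalization (0.0690) and cyclic loess (0.0815; 0.000692 to 0.0815 over the alternatives). Calcium handling and cardiac ion channel genes fell in 11 of 35 cases and rose in 4 (14 and 6 adjusted over the list alone; camera adjusted p = 0.0242, adjusted p = 0.208 with an estimated correlation). Scn4b, a sodium channel subunit, fell from 52.5 ± 4.24 to 24.3 ± 8.27. The mean of the calcium list was -0.14, and -0.09 with no rescaling. Its call was lost with quantile normalization (0.0999), cyclic loess (0.133), without WKY replicate 2 (0.0842) and without SHR replicate 1 (0.0532), with 0.00988 to 0.133 over the alternatives. Circadian clock genes fell in 5 of 20 cases and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0199, adjusted p = 0.208 with an estimated correlation). The clock repressor gene Per2 fell from 4.48 ± 0.628 to 2.29 ± 0.733, and Dbp and Per1 were at log2 changes of -1.17 and -0.74. The clock gene that rose was Arntl, from 3.56 ± 0.577 to 7.21 ± 2.84. The time of day of collection was not used here, so the list's direction cannot be read as lower clock activity. Without WKY replicate 2 the list's adjusted p was 0.0539 (0.00655 to 0.0539). In the sarcomere list 3 of 23 rose and 4 fell, 4 and 5 adjusted over the list alone (camera adjusted p = 0.397). Unfolded protein response genes rose in 12 of 27 cases and fell in 0 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000397, adjusted p = 0.225 with an estimated correlation). The stress transcription factor Atf4 rose by 0.79.

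Single genes outside these groups moved far. Ifit1, an interferon-induced gene, was at 0.0573 ± 0.0497 in WKY and 8.12 ± 2.51 in SHR, and Defb1, which encodes a beta-defensin, at 0.291 ± 0.252 and 15.1 ± 6.50. Chi3l1, a chitinase-like secreted protein, rose by 3.15 and Reg3b, a secreted lectin, by 2.79. The largest fall among named genes was that of Cyp2e1, a cytochrome P450, from 43.0 ± 14.2 to 2.66 ± 0.862. Retsat, retinol saturase, fell from 252 ± 32.4 to 34.9 ± 3.32 and Endog, the mitochondrial endonuclease G, from 38.9 ± 5.76 to 5.09 ± 0.641. Gstm2, the mu-class glutathione S-transferase named in the study's title, was at 273 ± 10.3 in WKY and 126 ± 12.5 in SHR (log2 change -1.11, adjusted p = 4.93e-05). The interferon list as a whole (3 of 44 rose and 3 fell, 2 and 3 adjusted over the list alone) was not called (camera adjusted p = 0.79).

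Across all genes, limma called 2561 of 11717 tested genes between SHR and WKY, 1398 higher and 1163 lower in SHR. Of these, 296 higher and 99 lower genes changed at least 2-fold. Higher genes made up 54.6% of the calls, and 64.6% with the deposited FPKM not rescaled. The values of the groups did not overlap in 40.9% of tested genes, where chance gives 10%. Without SHR replicate 3 the count was 1551 (892 higher and 659 lower), and without WKY replicate 1 or WKY replicate 2 the lower genes numbered 755 and 745. Of 33 tested lists, 14 passed with the preset correlation, 9 up and 5 down, and 1 with an estimated correlation.

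The remaining lists gave smaller or mixed counts in SHR against WKY. Pericyte markers passed (3 of 9 rose and 1 fell, 6 and 1 adjusted over the list alone; camera adjusted p = 0.0308, adjusted p = 0.486 with an estimated correlation). They did not pass without WKY replicate 1 (0.0671), WKY replicate 2 (0.0664), SHR replicate 1 (0.0532) or SHR replicate 2 (0.0651), with 0.00264 to 0.0671 over the alternatives. Smooth muscle markers were not called (3 of 10 rose and 0 fell, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0833). They passed with cyclic loess (0.0480), without WKY replicate 3 (0.0484) or SHR replicate 2 (0.0310; 0.0310 to 0.150 over the alternatives). Of Schwann and nerve markers 3 of 8 rose and 0 fell, 3 and 0 adjusted over the list alone, at a camera adjusted p of 0.13, and 0.0294 without SHR replicate 3 (0.0294 to 0.406). In the renin-angiotensin-aldosterone list 4 of 11 rose and 0 fell, 4 and 0 adjusted over the list alone (camera adjusted p = 0.237). Ace, the angiotensin-converting enzyme gene, was at 3.19 ± 0.695 and 4.98 ± 0.305 (adjusted p = 0.0142, and 0.0525 without SHR replicate 3; 0.00985 to 0.0525). Agtr1a, the gene of the receptor that allisartan blocks, was at 0.885 ± 0.550 and 0.816 ± 0.346 (adjusted p = 0.99). Among antioxidant and glutathione enzymes 5 of 35 rose and 5 fell, 5 and 5 adjusted over the list alone. Gpx3, the secreted glutathione peroxidase, rose by 1.15 and Gstz1 was at -1.03. The list's median of -0.02 and mean of 0.03 differed in sign (camera adjusted p = 0.938, direction down). Nqo1 and Hmox1 are targets of Nrf2, a transcription factor that responds to oxidants. These 2 genes were at 10.3 ± 1.31 and 43.0 ± 8.37 in WKY and 14.3 ± 2.62 and 58.6 ± 6.93 in SHR (adjusted p = 0.041 and 0.0683). The Nqo1 call was lost in 8 alternatives, 6 of which left out 1 library, with 0.0261 to 0.142, and Hmox1 passed in 4, among them without WKY replicate 3 (0.0280) or treated SHR replicate 2 (0.0376), with 0.0280 to 0.217.

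No list-wide change was called in SHR against WKY for the following groups. Of 9 MHC class II and antigen presentation genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.397). Of 27 apoptosis genes, 7 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.259). Of 40 autophagy and lysosome genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.259). Of 18 heat shock and proteostasis genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.938). Of 24 immediate-early genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.901). Of 29 cell cycle genes, 1 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.79). Of 5 mu-class glutathione S-transferases, 0 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.243). Of 6 atrial cardiomyocyte markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.79). Of 14 endothelial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.938). Of 7 lymphatic endothelial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.397). Of 8 erythroid markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.259). Cytosolic ribosomal protein genes (2 of 48 rose and 0 fell, 1 and 0 adjusted over the list alone) were not called (camera adjusted p = 0.79). They were with quantile normalization (0.00922), cyclic loess (0.00298) and without WKY replicate 1 (0.0139), over a range of 0.00298 to 0.907. Mean and test differed in sign for the interferon (0.04), heat shock (0.00108), endothelial (-0.01) and atrial (0.13) lists. Among single members, the MHC class II gene RT1-Ba fell from 3.43 ± 1.01 to 0.516 ± 0.359 while RT1-Db1 rose from 0.848 ± 0.409 to 3.48 ± 0.903, and near-identical copies make both uncertain. Fos, an immediate-early transcription factor, fell from 13.0 ± 1.78 to 3.77 ± 1.36.

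**Figure D1:**
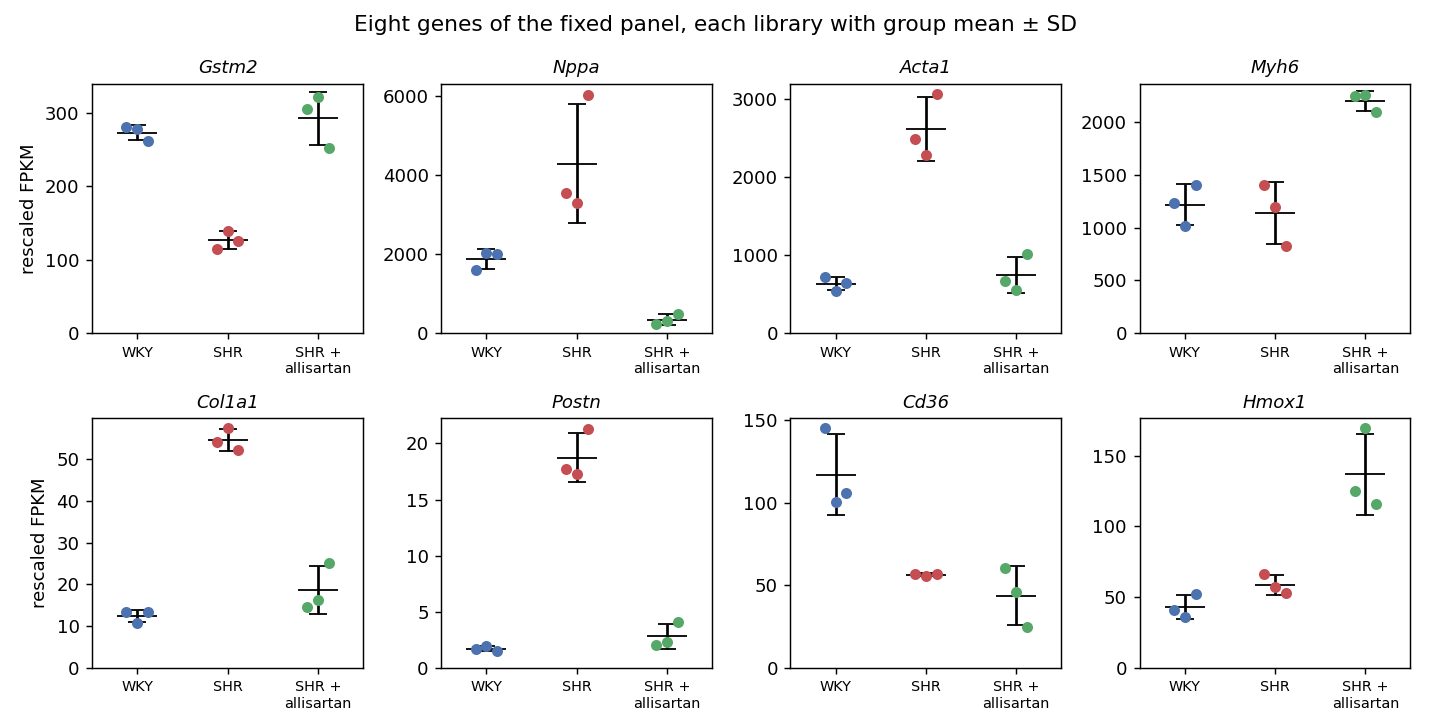
Rescaled FPKM of 8 panel genes (Gstm2, Nppa, Acta1, Myh6, Col1a1, Postn, Cd36 and Hmox1) in the 3 groups, with each library as a point and the mean ± SD as a bar and whisker. Gstm2 was at 273 ± 10.3 in WKY, 126 ± 12.5 in SHR and 293 ± 36.2 in treated SHR (n = 3 libraries per group).

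The comparison of treated SHR with SHR asks what 34 weeks of allisartan changed in the hypertensive heart. Gstm2 was at 293 ± 36.2 in treated SHR against 126 ± 12.5 in SHR, a log2 change of 1.21 (SE 0.0989, adjusted p = 3.06e-05). All 3 treated libraries lay above all 3 SHR libraries, which gives a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Gstm1 and Gstm7, of the same class of detoxifying enzymes, rose by 1.23 and 1.25, Gstm3 fell by 0.72 and Gstm4, given to complete the class after its values were seen, was at 4.14 ± 0.619 and 4.002 ± 0.307 (adjusted p = 0.857). Gstm6 and Gstm6l were listed at 0 in every library, and reads shared between these near-identical genes make single members uncertain. As a list the mu-class genes (3 of 5 rose and 1 fell, 3 and 1 adjusted over the list alone) did not pass (camera adjusted p = 0.0573). They did with no rescaling (0.0370), with no filter on low values (0.0400), without SHR replicate 2 (0.0405) and without treated SHR replicate 3 (0.0313), over a range of 0.0313 to 0.0901. Other antioxidant genes went both ways: Hmox1, heme oxygenase 1, rose from 58.6 ± 6.93 to 137 ± 28.8 and Srxn1, sulfiredoxin, from 11.5 ± 1.28 to 19.2 ± 2.70, while Gpx3 fell from 216 ± 22.2 to 133 ± 8.57. In that list 8 of 35 rose and 10 fell, 9 and 10 adjusted over the list alone (camera adjusted p = 0.931, direction down). Its median was -0.07 and its mean 0.02, which was below 0 with no rescaling, quantile and cyclic loess normalization. Nqo1 was at 14.3 ± 2.62 and 14.2 ± 1.60.

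Matrix genes fell. Thbs4 went from 49.8 ± 7.18 in SHR to 3.80 ± 2.27 in treated SHR (log2 change -3.66, SE 0.277). Timp1, an inhibitor of matrix metalloproteinases, fell from 42.3 ± 4.63 to 7.06 ± 2.75 and Postn from 18.7 ± 2.18 to 2.80 ± 1.10. Col1a1 and Col3a1 fell by 1.56 and 1.70 (SE 0.170 and 0.182). In the extracellular matrix list 0 of 48 tested members rose and 40 fell (0 and 41 adjusted over the list alone). The mean log2 change was -1.24 ± 0.863 (camera adjusted p = 6.55e-19, adjusted p = 0.335 with an estimated correlation). Fibroblast markers fell in 12 of 13 cases and rose in 0 (the same counts adjusted over the list alone; camera adjusted p = 2.28e-07, adjusted p = 0.28 with an estimated correlation). Those called ranged from -1.75 for Mfap5 to -0.30 for Dpt. Of the genes of long transcripts, a list written after the data were seen, 26 of 50 tested members fell in treated SHR and 0 rose. Their median log2 change was -0.33, against 0.04 in SHR against WKY (6 higher and 3 lower). Ogn, which encodes the small matrix proteoglycan osteoglycin and was in no list, rose from 0.577 ± 0.267 to 9.66 ± 2.02 (log2 change 3.25). Tgfb1 was at 15.6 ± 1.87 and 16.6 ± 1.45 (adjusted p = 0.516).

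The fetal cardiac genes fell with treatment. Nppa went from 4289 ± 1507 to 339.6 ± 130.02 (log2 change -3.67, SE 0.268, adjusted p = 2.16e-05), Acta1 from 2612 ± 407 to 744 ± 235 and Nppb from 698 ± 76.6 to 230.3 ± 63.6. Of the list, 0 of 18 tested members rose and 13 fell (1 and 15 adjusted over the list alone; camera adjusted p = 2.28e-07, adjusted p = 0.28 with an estimated correlation). Nppa is also in the list of atrial cardiomyocyte markers, whose mean log2 change was -1.01 ± 1.46 (SD over genes, camera adjusted p = 0.282). Myh7 fell by 0.72 while Myh6 rose from 1144 ± 295 to 2204 ± 91.3 (adjusted p = 0.00178). Atp2a2 was at 1833 ± 127 and 1815 ± 45.7 (adjusted p = 0.906). In the sarcomere list 10 of 23 rose and 9 fell, 10 and 9 adjusted over the list alone (camera adjusted p = 0.758). Ttn (titin) and Flnc (filamin C), both of long transcripts, fell by 1.42 and 1.32, and Tnni3, cardiac troponin I, rose by 1.19. The mean of that list was 0.00154 and its median -0.02, and the mean was below 0 with quantile normalization (-0.12), cyclic loess (-0.11) and no rescaling (-0.06). Ventricular cardiomyocyte markers rose in 6 of 10 cases and fell in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.48 with an estimated correlation). Their mean was 0.35, against 0.16 with quantile and 0.22 with cyclic loess normalization, and the call ended with quantile normalization (0.264) and cyclic loess (0.0618; 0.00879 to 0.264 over the alternatives).

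The oxidative phosphorylation and fatty acid lists were called up in treated SHR. In the nuclear-encoded oxidative phosphorylation list 34 of 63 tested members rose and 7 fell (36 and 7 adjusted over the list alone; camera adjusted p = 2.9e-07, adjusted p = 0.501 with an estimated correlation). Ndufa12, a subunit of complex I, rose from 55.7 ± 12.4 to 286 ± 33.6 (log2 change 2.37), and the cytochrome c oxidase subunit genes Cox6a2 and Cox5b rose by 1.22 and 0.92. The list's mean change was 0.29, and 0.18 with cyclic loess normalization. The SD over its genes was 0.498, against 0.176 in SHR against WKY. A library or RNA difference of the treated libraries stays open for this list, as does an effect of the drug. Of the fatty acid genes 19 of 40 rose and 2 fell, 19 and 2 adjusted over the list alone (camera adjusted p = 2.49e-05, adjusted p = 0.501 with an estimated correlation). Pnpla2, adipose triglyceride lipase, rose from 4.02 ± 0.433 to 25.8 ± 10.7 and Ppargc1a, a coactivator of mitochondrial genes, from 10.1 ± 0.873 to 20.6 ± 3.66. Angptl4, an inhibitor of lipoprotein lipase, fell by 1.29. Cd36 was at 56.4 ± 0.876 and 43.8 ± 18.0 (adjusted p = 0.204, and 0.0409 without treated SHR replicate 1; 0.0409 to 0.691 over the alternatives). Glucose uptake and glycolysis genes rose in 9 of 28 cases and fell in 4 (the same counts adjusted over the list alone; camera adjusted p = 0.277), and Eno1 was at 356 ± 18.4 and 377 ± 21.2. Cyp2e1 rose from 2.66 ± 0.862 to 29.3 ± 13.8. The cytosolic ribosomal proteins, whose genes as a rule move together, spread apart in treated SHR: the SD of their log2 changes was 0.401, against 0.150 in SHR against WKY. Of these genes 4 of 48 rose and 13 fell, 6 and 15 adjusted over the list alone. That list was called down with quantile normalization (0.000976) and cyclic loess (0.000632) and not otherwise (camera adjusted p = 0.277; 0.000632 to 0.636 over the alternatives).

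The macrophage, complement and inflammatory lists were called down in treated SHR. Macrophage markers fell in 10 of 14 cases and rose in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000765, adjusted p = 0.501 with an estimated correlation). Lyz2 fell from 263 ± 27.6 to 135 ± 12.3 and Mrc1, the mannose receptor, from 9.61 ± 1.16 to 4.71 ± 1.34. In the complement list 0 of 20 rose and 16 fell, 1 and 16 adjusted over the list alone (camera adjusted p = 2.91e-06, adjusted p = 0.436 with an estimated correlation), with C4b from 8.28 ± 0.486 to 1.87 ± 0.520. In the list of inflammatory cytokines and adhesion genes 0 of 29 rose and 16 fell, 2 and 17 adjusted over the list alone (camera adjusted p = 0.000902, adjusted p = 0.191 with an estimated correlation). Ccl7 and Ccl2 fell by 1.78 and 1.66. For NADPH oxidase and other oxidant sources 0 of 10 rose and 5 fell, 1 and 5 adjusted over the list alone (camera adjusted p = 0.0946, and 0.0488 with quantile normalization; 0.0488 to 0.190 over the alternatives). Cybb and Maoa fell by 1.20 and 1.53. MHC class II and antigen presentation genes (1 of 9 rose and 4 fell, 1 and 4 adjusted over the list alone) lay at 0.0549 and passed in 11 alternatives, of which 5 left out 1 library (0.0104 to 0.109). The lysosomal protease gene Ctss of that list fell from 19.7 ± 0.480 to 8.81 ± 0.694. Ace fell by 0.89 (adjusted p = 0.00105) and Agtr1a was at 0.816 ± 0.346 and 0.894 ± 0.406. In the renin-angiotensin-aldosterone list 0 of 11 rose and 3 fell, 1 and 3 adjusted over the list alone (camera adjusted p = 0.282). Agt, angiotensinogen, was too low to test, at 0.144, 0.109 and 0.117 in the SHR libraries and listed at 0 in the 3 treated libraries.

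Haemoglobin genes were among the largest rises in treated SHR. Hba1 was at 1497, 612 and 620.5 in the 3 treated libraries, 187, 169 and 98.9 in SHR, and 167, 361 and 247 in WKY. The ratio of Hba1 to Hbb was 5.14 to 7.26 in treated SHR and 2.37 to 2.99 in the other 6 libraries. The copy Hba-a1 was listed at 0 in all 3 treated libraries and at 17.6, 3.53 and 3.09 in SHR, and near-identical copies make these levels uncertain. Erythroid markers rose in 6 of 8 cases and fell in 1 (the same counts adjusted over the list alone; camera adjusted p = 0.0302, adjusted p = 0.501 with an estimated correlation). Their mean was 0.86, and 0.56 without SHR replicate 3. The call was lost without that library (0.0901) and with array weights (0.0535; 0.00773 to 0.0901 over the alternatives). Other lists were not called. Of 35 calcium handling and ion channel genes, 13 rose and 5 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.223). Of 27 unfolded protein response genes, 8 rose and 6 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.943). Of 18 heat shock and proteostasis genes, 7 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.223). Of 20 circadian clock genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.221). Of 24 immediate-early genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.282). Of 29 cell cycle genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.2). Of 27 apoptosis genes, 2 rose and 8 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.282). Of 40 autophagy and lysosome genes, 6 rose and 11 fell (8 and 12 adjusted over the list alone, camera adjusted p = 0.223). The last list passed with quantile normalization (0.0442; 0.0442 to 0.366). Trdn, triadin of the calcium release complex, rose from 21.1 ± 3.21 to 53.3 ± 1.05, Usp2, a clock-controlled protease, from 17.8 ± 0.756 to 47.1 ± 0.916 and Hspe1, a mitochondrial chaperonin, from 282 ± 8.09 to 536 ± 48.6.

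Across all genes, limma called 3924 of 11717 genes between treated SHR and SHR, 1888 higher and 2036 lower in treated SHR, of which 142 and 240 changed at least 2-fold. The values of the groups did not overlap in 46.4% of tested genes, where chance gives 10%. Of 33 lists 10 passed with the preset correlation (4 up and 6 down) and 0 with an estimated correlation, where camera's lowest adjusted p was 0.191 and 4 lists had an unadjusted p under 0.05. Cell type markers outside the groups above, and interferon genes, were not called. Of 44 interferon response genes, 1 rose and 2 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.638). Of 6 atrial cardiomyocyte markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.282). Of 14 endothelial markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.571). Of 7 lymphatic endothelial markers, 0 rose and 3 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.0946). Of 10 smooth muscle markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.481). Of 9 pericyte markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.282). Of 8 Schwann and nerve markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.638).

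**Figure D2:**
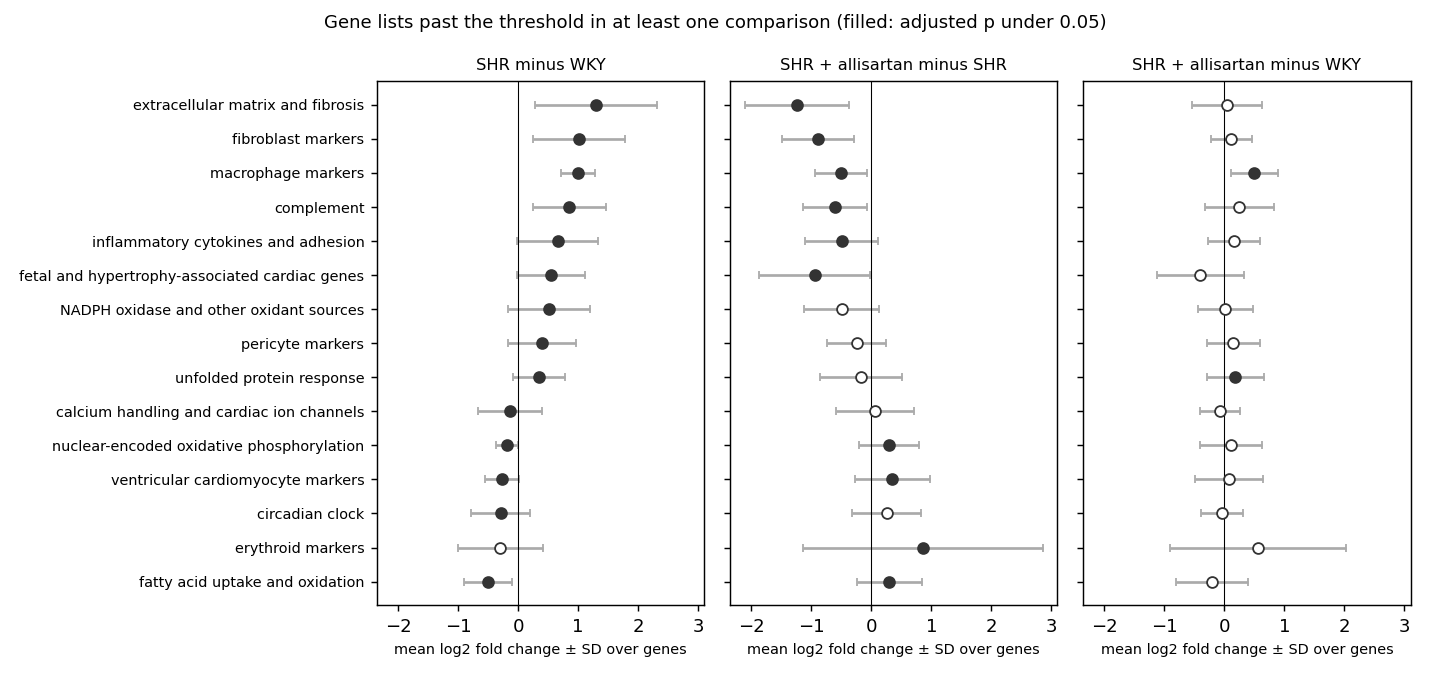
Mean log2 change of 15 gene lists, with the SD over their genes as whiskers, in each of the 3 comparisons, where filled points have a camera adjusted p under 0.05. The extracellular matrix list was at 1.29 in SHR against WKY, -1.24 in treated SHR against SHR and 0.05 in treated SHR against WKY.

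The comparison of treated SHR with WKY asks what still sets the heart of treated SHR apart. These groups differ in both strain and treatment. Several genes that differed between SHR and WKY also differed here. Ifit1 was at 8.68 ± 0.0638 against 0.0573 ± 0.0497 in WKY, Eno1 at 377 ± 21.2 against 43.7 ± 1.79 and RT1-A1, a class I histocompatibility gene, at 78.8 ± 5.58 against 13.4 ± 0.859. Endog was lower, at 4.07 ± 0.986 against 38.9 ± 5.76. Nppa, at 339.6 ± 130.02, lay below its WKY level of 1872 ± 245 (log2 change -2.52, adjusted p = 0.000161), as did Nppb (-1.07), Myh7 (-1.11) and Ctgf, a matrix-associated growth factor gene (-1.87). Mt1, a metallothionein, and Hmox1 were higher than in WKY by 2.61 and 1.66. Gstm2 was at 293 ± 36.2 and 273 ± 10.3 (log2 change 0.09, SE 0.0989, adjusted p = 0.532; exact permutation p = 0.5), and Gstm1 was higher than in WKY by 1.46.

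Of 33 lists 2 passed camera, both up, and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05. The count was 6 without WKY replicate 3, 4 without treated SHR replicate 1 and 4 without treated SHR replicate 3. Macrophage markers rose in 9 of 14 cases and fell in 0 (the same counts adjusted over the list alone; camera adjusted p = 0.000163, adjusted p = 0.934 with an estimated correlation). Fcer1g, an immunoglobulin receptor chain, was higher by 1.27 and Tyrobp, a signalling adaptor of myeloid cells, by 1.11. Of the unfolded protein response genes 14 of 27 rose and 1 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 0.00481, adjusted p = 0.934 with an estimated correlation). Manf, a secreted factor of the endoplasmic reticulum, was higher by 0.77. In the extracellular matrix list 7 of 48 rose and 7 fell, 7 and 7 adjusted over the list alone (camera adjusted p = 0.787). Thbs4 was still higher at 3.80 ± 2.27 against 1.11 ± 0.169. Postn and Col3a1 were at 0.53 and 0.41 (adjusted p = 0.0752 and 0.129), Postn at 0.0388 without treated SHR replicate 1 (0.0388 to 0.187). Col1a1 was higher by 0.53 (adjusted p = 0.0437), a call lost in 13 alternatives, 8 of which left out 1 library (0.0176 to 0.146). Without treated SHR replicate 3 its log2 change was 0.30 (adjusted p = 0.0786). Of 18 fetal genes, 1 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.0632). Of 40 fatty acid genes, 3 rose and 15 fell (3 and 16 adjusted over the list alone, camera adjusted p = 0.0632). Of 6 atrial markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0632). The fetal list passed with quantile normalization (0.0268), with the replicate block (0.0423) and without treated SHR replicate 1 (0.0452) or 3 (0.0491), over a range of 0.0268 to 0.172. The fatty acid list passed with quantile (0.0245) and cyclic loess normalization (0.0429) and with the replicate block (0.0444). It also passed without WKY replicate 2 (0.0321) or 3 (0.0106) or treated SHR replicate 2 (0.0142), over a range of 0.0106 to 0.384. The atrial list passed with the replicate block (0.0423) and without WKY replicate 3 (0.0429) or treated SHR replicate 3 (0.0278), over a range of 0.0278 to 0.306.

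Cd36 was lower in treated SHR than in WKY, at 43.8 ± 18.0 against 117 ± 24.4 (adjusted p = 0.00264), and so was Atp2a2, by a log2 change of -0.34 (adjusted p = 0.00513). Myh6 and Tgfb1 were higher by 0.87 and 0.69 (adjusted p = 0.00522 and 0.00105). Acta1, Ace and Agtr1a were at 0.20, -0.30 and 0.07 (adjusted p = 0.498, 0.149 and 0.905), with Ace at 0.0286 without WKY replicate 2 (0.0286 to 0.399). Nqo1 was higher by 0.45 (adjusted p = 0.0384), lost in 7 alternatives, 5 of which left out 1 library (0.0216 to 0.128). Of 63 oxidative phosphorylation genes, 20 rose and 12 fell (23 and 14 adjusted over the list alone, camera adjusted p = 0.292). Of 20 complement genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.153). Of 48 ribosomal protein genes, 6 rose and 11 fell (8 and 14 adjusted over the list alone, camera adjusted p = 0.43). The first passed without WKY replicate 1 (0.0394; 0.0394 to 0.592), the second without WKY replicate 3 (0.0465) or treated SHR replicate 1 (0.0452; 0.0452 to 0.267) and the third without WKY replicate 3 (0.0201; 0.0201 to 0.947). Of the genes of long transcripts 22 of 50 fell and 0 rose (median -0.29), with no list-wide test in this comparison. Across all genes, limma called 2852 of 11717 genes, 1513 higher and 1339 lower in treated SHR, of which 158 and 114 changed at least 2-fold. Without WKY replicate 2 the lower genes numbered 873. The values of the groups did not overlap in 40.1% of tested genes, where chance gives 10%.

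Setting both SHR comparisons side by side asks whether genes that differed between the strains moved back toward WKY with the drug. Of the 2561 genes called in SHR against WKY, 1436 (56.1%) were called in the opposite direction in treated SHR against SHR, 83 (3.24%) in the same direction and 1042 (40.7%) in neither. Of those that moved back, 1133 were not called against WKY, 108 were still called on the SHR side and 195 beyond WKY. Examples of the last class, chosen after their values were seen, were Ankrd23, a stretch-responsive ankyrin repeat gene, at 74.3 ± 5.84 in WKY, 140.3 ± 29.8 in SHR and 34.3 ± 6.09 in treated SHR, and Rbfox1, a splicing regulator, at 16.8 ± 0.216, 9.63 ± 1.94 and 30.7 ± 3.28. A further 589 genes were not called between the SHR groups and stayed on the SHR side of WKY, among them Ifit1, Defb1, Eno1, Rims1, Endog and RT1-A1. Creg1, a secreted glycoprotein of the endosomal and lysosomal pathway, was another, at 4.38 ± 0.936 in WKY, 24.7 ± 1.61 in SHR and 32.4 ± 4.15 in treated SHR. Another 2405 genes were called between the SHR groups and not in SHR against WKY, and 1314 of these were also called in treated SHR against WKY.

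The same 3 SHR libraries enter both comparisons with opposite signs, so opposite movement arises by chance. Across genes, which are not independent replicates, the covariance of the 2 sets of log2 changes was -0.112, against -0.0138 (-0.0158 to -0.0124) in 100 simulations of groups with no difference, a difference of -0.0979. The correlation was -0.570, against -0.500 simulated, and 69.7% of tested genes had opposite signs, against 66.8%. The simulated genes were drawn independently, so the simulated ranges leave out correlation between genes. Of the genes called in SHR against WKY, 86.1% had opposite signs. The 90.0% (0 to 100%) in those simulations that called any gene rests on few genes each and cannot serve as a reference. Genes called up in SHR and then down with treatment numbered 822, and 614 the other way, where independent calls would give 243 and 187. Called up in both were 53 and down in both 30, against 225 and 202. Independent calls take no account of the shared SHR libraries. With 3 SHR libraries the controls cannot be split, and part of the opposite movement may come from these shared libraries.

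**Figure D3:**
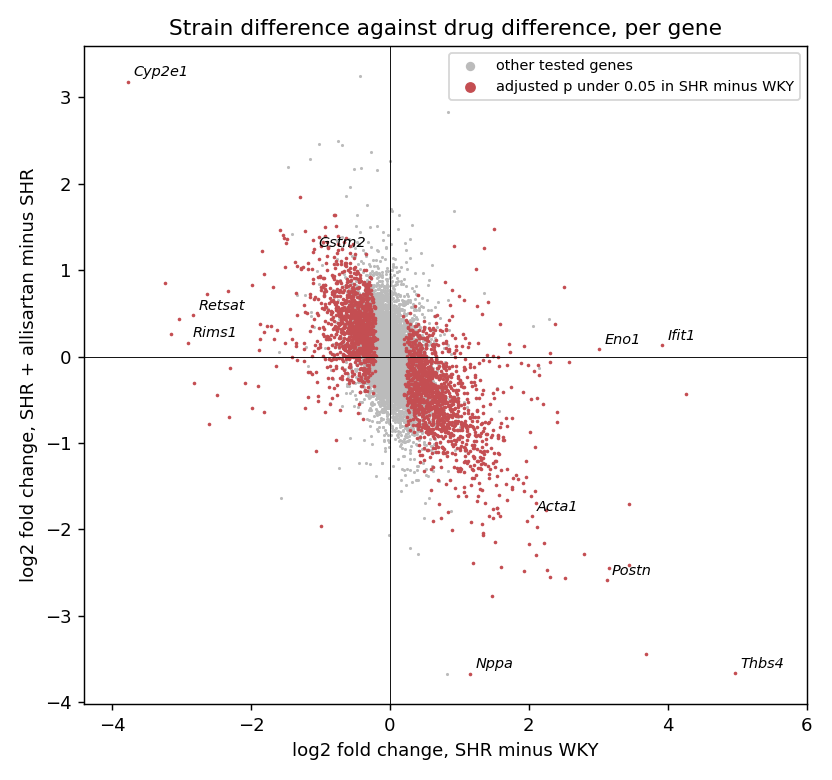
Log2 change of each tested gene in SHR against WKY (horizontal axis) and in treated SHR against SHR (vertical axis), with genes at an adjusted p under 0.05 in SHR against WKY in red. Of the 2561 red genes 1436 were called in the opposite direction on the vertical axis, and both axes use the same 3 SHR libraries.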

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

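Cyclic loess normalization and removal of the trend with genomic span were chosen after the data had been seen. The Gstm2 change kept its sign in all alternatives run. The covariance of both SHR contrasts is negative even in simulated groups with no difference, so its sign alone carries no information. In each alternative in which it was computed, it lay below the range of such simulations. Gstm2 in treated SHR minus SHR ranged from 1.11 (cyclic loess) to 1.31, and from 1.13 to 1.31 with 1 library left out. The covariance of both SHR contrasts was -0.133 to -0.103 with 1 library left out. Requiring a log2 change of 1 leaves fewer genes by construction: 395 (296 higher, 99 lower) for SHR minus WKY, 382 (142 and 240.0) for treated SHR minus SHR and 272 (158 and 114) for treated SHR minus WKY. With the correlation estimated, 1, 0 and 0 lists passed in these contrasts, where 6, 4 and 0 had an unadjusted camera p under 0.05. For treated SHR minus WKY, 4 lists passed with quantile normalization and 5 with the replicate block, which added the fetal (0.0423), fatty acid (0.0444) and atrial (0.0423) lists; the cause was not tested. The block gave 2544, 3851 and 2758 genes. The labels do not say that replicate numbers pair the libraries. Correlations of deviations from group means were -0.0623 to 0.0828 (mean 0.0132) over 9 pairs of the same number. For 18 pairs of other numbers they were -0.0694 to 0.0640 (mean -0.00659). Of 9 libraries 4 correlated best with one of their own number, so a weak pairing stays open. With 1 library left out, SHR minus WKY gave 1551 to 2623 genes (892 to 1442 higher and 659 to 1181 lower) and 11 to 15 lists, treated SHR minus SHR 2860.0 to 3838 genes and 10 to 12 lists, and treated SHR minus WKY 1909 to 2766 genes (873 to 1272 lower) and 2 to 6 lists. The results that changed sign were uncalled genes or the means of uncalled lists, and the cause was not tested. By setting they were as follows. Deposited FPKM with no rescaling: in SHR minus WKY sarcomere (0.0142), endothelial markers (0.0408), Agtr1a (0.0231), in treated SHR minus SHR antioxidant (-0.0348), sarcomere (-0.0586), glycolysis (-0.0191), interferon response (-0.0165). Quantile normalization: in SHR minus WKY sarcomere (0.0363), interferon response (-0.00671), cell cycle (-0.0317), in treated SHR minus SHR antioxidant (-0.0275), sarcomere (-0.12), glycolysis (-0.0138), in treated SHR minus WKY ventricular markers (-0.00994). Pseudocount 1: in treated SHR minus SHR sarcomere (-0.00340). Pseudocount 0.1: in SHR minus WKY Agtr1a (0.0611), in treated SHR minus SHR Nqo1 (0.00015). No filter on low values: in SHR minus WKY heat shock (-0.00939), in treated SHR minus SHR sarcomere (-0.00366). Array weights: in SHR minus WKY endothelial markers (0.0166), in treated SHR minus SHR sarcomere (-0.00419). Cyclic loess normalization: in SHR minus WKY sarcomere (0.0738), cell cycle (-0.0257), Myh6 (0.0399), in treated SHR minus SHR antioxidant (-0.0306), sarcomere (-0.11), glycolysis (-0.0332). Trend with genomic span removed: in SHR minus WKY heat shock (-0.0113), in treated SHR minus SHR Atp2a2 (0.0183), Nqo1 (0.00807). With 1 library left out, the ranges of further results crossed 0. In SHR minus WKY they were interferon response -0.0671 to 0.17, endothelial markers -0.0733 to 0.0501, heat shock -0.0223 to 0.0376, Agtr1a -0.40 to 0.20, immediate-early genes -0.14 to 0.0221, cytosolic ribosomal proteins -0.0373 to 0.13, Myh6 -0.28 to 0.11. In treated SHR minus SHR they were Nqo1 -0.0737 to 0.14, antioxidant -0.00055 to 0.0721, sarcomere -0.0240 to 0.0203, Agtr1a -0.15 to 0.28, interferon response -0.0299 to 0.14, Atp2a2 -0.0672 to 0.0330. In treated SHR minus WKY they were NADPH oxidase -0.0623 to 0.0897, renin-angiotensin-aldosterone system -0.0103 to 0.0932, interferon response -0.0145 to 0.21, autophagy and lysosome -0.0218 to 0.0103, Agtr1a -0.33 to 0.27, endothelial markers -0.12 to 0.00228, apoptosis -0.0667 to 0.0224, extracellular matrix and fibrosis -0.11 to 0.16, circadian clock -0.10 to 0.0353, Acta1 -0.0394 to 0.39. The other results were counted once per alternative, so 1 result can count many times. Under other alternatives 140 of these counts weakened and 31 strengthened past the threshold, beside 5365 that stayed the same. With 1 library left out, 277 weakened and 30 strengthened, summed over the left-out libraries, beside 4103 the same. The most that weakened for 1 library were 43, without WKY replicate 1. Depth is unknown and sets no stated limit.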

Other observations

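The pathway tests, the genes named from them, and all tests of explanations except the counts over other splits of the libraries, were chosen only after the results were seen. Of the 122 tested genes of the deposited spliceosome annotation, which serve the removal of introns from RNA, 44 rose and 14 fell in treated SHR against SHR. U2af1, a splice site factor, rose from 13.8 ± 2.52 to 27.4 ± 1.81 and Prpf38b from 8.05 ± 0.699 to 15.2 ± 0.958. Hspa2, a chaperone in the same annotation, fell by 0.92. Proteasome genes, which encode the main protein-degrading complex, rose in 19 of 41 cases and fell in 4, with Psmb7 from 108 ± 5.85 to 199 ± 10.9 and Psmb4 from 83.3 ± 8.56 to 62.9 ± 0.761. Citrate cycle genes rose in 12 of 29 cases and fell in 0, with Idh3g from 275 ± 12.5 to 436 ± 22.5, after 1 had risen and 12 had fallen in SHR against WKY. Camera adjusted p-values over 267 pathways were 0.00155, 0.00161 and 0.00155, and 0.589, 0.607 and 0.607 with an estimated correlation. Camera called 43 pathways in SHR against WKY, 25 in treated SHR against SHR and 0 in treated SHR against WKY, with 0.516 for the spliceosome in the last (unadjusted p = 0.00278). With an estimated correlation, the lowest camera adjusted p among the 25 pathways of smallest p was 0.507 in SHR against WKY. Among the 25 called in treated SHR against SHR it was 0.589. The treated libraries also stood apart in the median change of long-transcript genes (-0.33), in the SD of the changes of ribosomal protein genes (0.401, against 0.150 in SHR against WKY) and in the ratio of Hba1 to Hbb (5.14 to 7.26, against 2.37 to 2.99 in the other libraries). A library or RNA difference therefore stays open for these pathways and for the oxidative phosphorylation list, as does an effect of the drug.

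Gstm2 was higher in treated SHR than in SHR by 1.21 (log2). The summed FPKM of the 7 mu-class genes was 171 ± 13.9 in SHR and 377 ± 46.2 in treated SHR. This difference of 206 exceeds the sum of both SDs, 60.1. Most of the sum is Gstm2 itself, and the other summed genes were too low to lend that much. This argues against reads moved among these 7 genes as the whole cause. The list asked for 9 genes, and copies outside the 7 are not covered by the sum. Of 48 ribosomal protein genes 1 (2.08%) moved by as much as Gstm2, so a random spread of genes in the treated libraries stays open, as does an effect of the drug, which the design names.

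Matrix genes fell with treatment. Their median log2 change lay below that of the long-transcript genes by a difference of -0.66 (95% bootstrap interval -1.06 to -0.36). This argues against a lower yield of long transcripts as the whole cause. The interval resamples genes, which are not independent, so it does not measure the spread between libraries. Any matrix genes also in the long list, which was written after the data were seen, counted only as long-transcript genes. The 13 fibroblast markers moved by -1.75 to -0.04, apart by more than their standard errors. Cochran's test of heterogeneity across these genes gave 1.08e-48, which argues against a smaller share of fibroblasts as the whole cause. A smaller share of fibroblasts, a change within fibroblasts and an effect of the drug stay open.

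Long-transcript genes had a median change of -0.33 in treated SHR against SHR. The medians of random lists matched on expression ran from -0.26 to 0.22, a percentile of 0 for this list, which argues against a trend with expression level. Against WKY the median was -0.29. A library or RNA difference of the 3 treated libraries and an effect of the drug cannot be told apart, since these libraries are also the treated group.

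For each contrast, the 6 libraries make 10 splits, too few for a share under 0.05. The real split called 2561, 3924 and 2852 genes in SHR minus WKY, treated SHR minus SHR and treated SHR minus WKY, and the highest other split called 2, 1 and 1. In each contrast 1 of the 10 splits, the real one, gave as many genes. Every other split mixes the 2 groups, so any difference between them widens its spread and lowers its count. The low counts therefore do not show what chance alone would give.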
